A study of Nicotiana tabacum with 12 samples.

How the data were processed

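Leaf RNA was measured by RNA sequencing in 12 libraries of burley tobacco, Nicotiana tabacum cultivar TN90, a light air-cured type. The groups are untransformed plants, called CK in the labels, and 3 lines carrying NtYb1, also called NtEGY2, behind the 35S promoter: P2.4a, P3.9a and P9.10a. Each group has 3 libraries that the labels call biological replicates, and the lines are segregants of primary transformants. Per the labels' protocols, the plants grew in the field, upper leaves were frozen before they matured, and libraries were made with a directional kit from purified total RNA. The treatment text in the labels names a P3 plant with another number than the sample titles do, and it also holds wording on root inoculation; groups here follow the titles and the line field.

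The authors deposited whole-number counts of reads per gene, not normalized, for all 12 libraries. HISAT2 2.1.0, SAMtools and bedtools 2.25.0 appear in the submitters' processing notes. The genome build, the annotation, the counting rule and the use of strand are not given in the sources used here, so no coordinates are printed. Reads from genes with a near-identical copy, which are common in this allotetraploid, could be split or lost by a counting rule that is not known. Identifiers of the count table were matched to a reference gene table of assembly ASM71507v2 (cultivar K326), used for names and for which genes neighbour each other. Of 61526 identifiers, 49014 were in that table and 1081 had a symbol or synonym. Unmatched identifiers held 4.43% of all counts. The table has symbols but no product names, so a gene without a symbol is given by its identifier.

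Totals ran from 13536964 to 18444571 counts per library. No pair of libraries held identical values, and the lowest chi-square per degree of freedom over all pairs was 5.21, so each library counted as its own sample. P-values measure the spread between the libraries of 1 field experiment; whether a library holds 1 plant or several is not given in the sources used here.

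Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (minimum count 10), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. All 12 libraries shared 1 fit with 8 residual degrees of freedom, which left 39207 genes, 906 of them with a symbol. The common biological coefficient of variation was 16.4%. The contrasts were the mean of the 3 lines minus CK, each line minus CK, and an F test among the 3 lines with the 3 pairwise differences. Fold changes are fitted log2 values with their standard error (SE). Levels are counts scaled by library size (CPM) with the SD over 3 libraries.

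Simulated counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold in all 3 lines, and as many other genes changed in P3.9a alone, were used to test the fit, on 38881 genes. For the mean of the 3 lines it recovered, of the genes changed in all lines, 25.4% of those changed 1.5-fold, 82.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 8 false calls among 181. For P3.9a against CK the shares of the genes changed in P3.9a alone were 13.4%, 68.7% and 95.5%, with 20 false calls among 255. Both totals of calls include genes of either set, and a false call is a gene in neither. The simulation drew each gene's spread independently and held no library that stood apart from its group.

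Gene lists were set as themes before the data were examined, as patterns on product names. Because the reference gave symbols only, their members were picked by symbol after the identifiers were seen and before any comparison was computed. The lists cover photosystem and light harvesting, the Calvin cycle, chlorophyll biosynthesis, chlorophyll breakdown and senescence, nitrate and ammonium assimilation, starch and sucrose, alkaloids, jasmonate and wounding, pathogenesis-related proteins, heat shock, phenylpropanoids, carotenoids, chloroplast proteases, plastid and cytosolic ribosomes, water deficit and abscisic acid, ethylene, phosphate and sulfate starvation, and markers of dividing cells, flower, root, trichome and stem. The 15 lists with 5 or more tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), with an estimated correlation and with fry. Adjustment was over these 15 lists, the family that the plan named; that choice was settled after values adjusted over all 25 tested lists had also been seen, and both counts are given. Another 10 tested lists were added on reading the symbols and were adjusted over all 25.

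The rule for named genes was set before the data were examined. It takes, for the mean of the 3 lines, up to 6 rises and 6 falls past the threshold with mean log2 CPM of 1 or more and all 9 transgenic libraries on 1 side of CK; for each list the 2 members with the smallest p; and for each line and among lines the leading genes under the same limits. Where no gene with a name passes, those with the smallest p are named and said not to pass; where genes have no name, at most 2 rises and 2 falls are given by identifier. Its part on EGY genes was void, since no symbol matched.

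Alternatives planned before the data were examined were other scalings, DESeq2 1.42.0, limma with line as a random block, other filters, a fold limit, the replicate number as a block, library sizes without the 20 most abundant genes, fits of 6 libraries, and each library left out. Thinning to equal depth, means of 2 lines, an adjusted p of 0.1, adjustment over the named genes alone and adjustment over all 25 lists were added after seeing the data. Where no CK count was seen, a floor of 3 counts over the group was used, which covers counting error only.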

Results

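The data are read counts per gene from leaves of field-grown burley tobacco in 12 libraries, 3 from untransformed TN90 (CK) and 3 from each of the lines P2.4a, P3.9a and P9.10a, which carry NtYb1 (NtEGY2) behind the 35S promoter. The stated question is which routes of carbon and nitrogen metabolism differ when a functional copy of this gene is present. Totals ran from 16657112 to 18444571 counts in CK and from 13536964 to 16788583 in the transgenic libraries. Log2 CPM correlated at a median of 0.975 across pairs of libraries within groups and 0.972 between groups. P3.9a replicate 1 stood apart: it lay at -77.4 on the first principal component, which held 26.3% of the variance, while the other 11 libraries lay between -26.5 and 40.3. Its median absolute difference from the other libraries of its group was 0.311 in log2 CPM, against 0.165 to 0.232 for the other 11. On the second component, with 16.3% of the variance, CK replicate 3 lay at 62.8 and the other 11 libraries between -32.3 and 22.2; without it 4 of the 11 gene lists reported below passed.

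The transgene would be the first check of the labels. No gene of the EGY family was matched to a symbol in the reference table, so its level is not analysed here and the labels of the 4 groups were not checked against it.

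Leaves of the transgenic lines differed from CK in 15 genes in the mean of the 3 lines, 3 higher and 12 lower, none of which has a symbol. LOC107772409 fell most among those on 1 side of CK in all 9 transgenic libraries: from 15.5 ± 0.438 CPM in CK (SD, n = 3) to 2.31 ± 0.761 in P2.4a, 1.43 ± 0.297 in P3.9a and 3.11 ± 1.43 in P9.10a, a fitted change of -2.83 (SE 0.21, edgeR adjusted p = 4.79e-05). LOC107780718 fell by 2.15 on the log2 scale (SE 0.23, adjusted p = 0.00289), from 183 to 320 counts per library in CK to 27 to 79 in the transgenic libraries. LOC107775051 rose 2.49-fold (log2 change 1.32, SE 0.21, adjusted p = 0.0464), and LOC107786896 rose 2.34-fold (1.23, SE 0.15, adjusted p = 0.00475), from 112 to 135 counts in CK to 180 to 416. The third rise, LOC107811420 (1.82, adjusted p = 0.00289), rested on P3.9a: without that line its value was 0.24 (adjusted p = 0.728), and it did not pass in limma (adjusted p = 0.621). LOC107772409, LOC107780718, LOC107786896 and LOC107811420 passed with each of the 12 libraries left out in turn, and LOC107775051 in 4 of these 12 fits. All 15 kept their sign.

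At an edgeR unadjusted p under 0.05 stood 4452 genes, 1802 higher and 2650 lower. Chance gives 1960.4 of the 39207 genes in both directions together. LOC107774583 was the other of the 15 that limma did not call (adjusted p = 0.0669). The count of 15 moved with the tool and the libraries: DESeq2 called 453 genes, limma with line as a block 486 and edgeR without a low-count filter 82, and the alternatives with all libraries ranged from 1 to 486. The correlation within lines that limma estimated was negative (-0.102), so its block allowed for no spread between lines. Leaving out P3.9a replicate 1 gave 740 genes, CK replicate 2 gave 48, P9.10a replicate 2 gave 42, P2.4a replicates 1 and 2 gave 8 and 9, P9.10a replicate 1 gave 9 and CK replicate 1 gave 6.

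**Figure D1:**
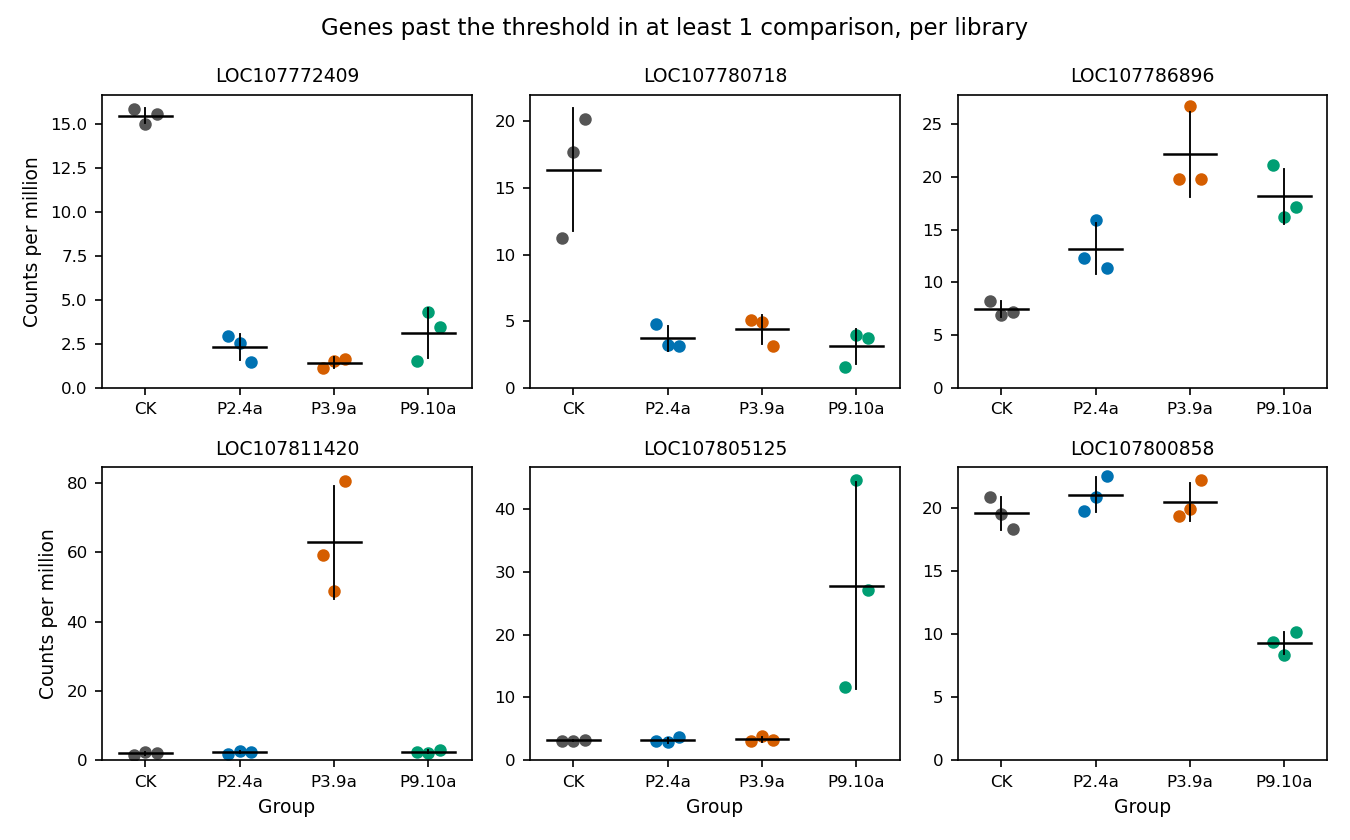
Counts scaled by library size, CPM (vertical axes, linear, from 0), of 6 genes in each library of CK, P2.4a, P3.9a and P9.10a; points are libraries, horizontal bars are means and vertical bars are 1 SD (n = 3). LOC107772409 and LOC107780718 lie below CK in all 9 transgenic libraries, while LOC107811420 is high in P3.9a and LOC107805125 in P9.10a.

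**Figure D2:**
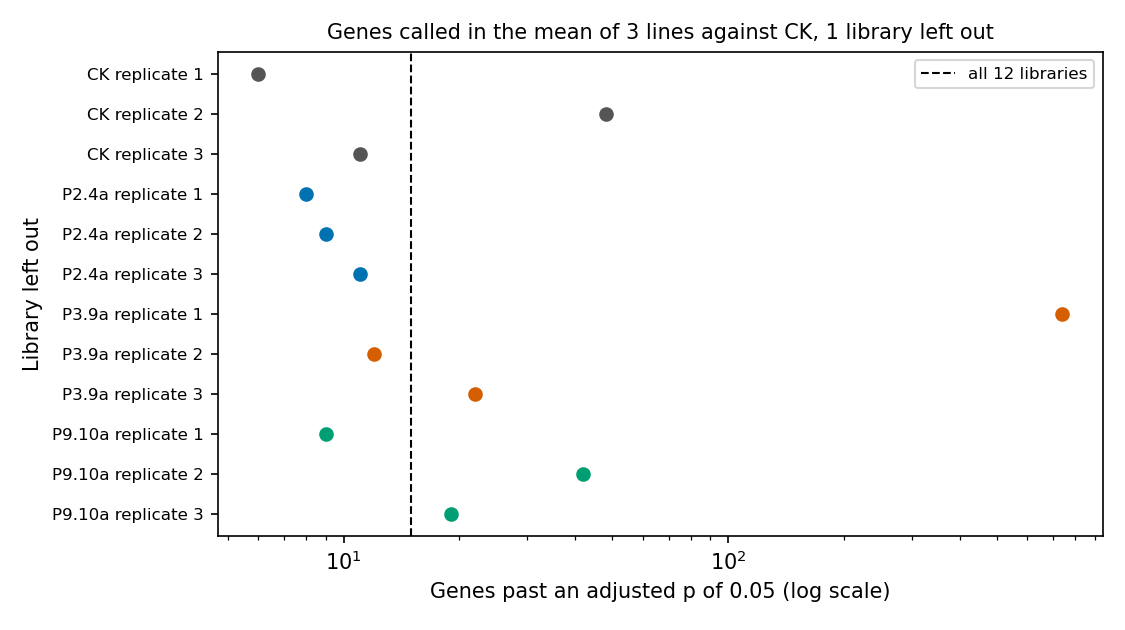
Number of genes past an adjusted p of 0.05 (horizontal axis, log scale) in the mean of 3 lines against CK when the library on the vertical axis is left out; points are coloured by group and the dashed line marks the count with all 12 libraries. The count was 740 without P3.9a replicate 1 and lay between 6 and 48 without any of the other libraries.

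None of the 906 genes with a symbol passed over all genes in edgeR, while 132 of them had an unadjusted p under 0.05. DESeq2 called 24 of them, limma 21, and edgeR without P3.9a replicate 1 called 35. Of all genes, 197 had an adjusted p under 0.1. The genes with a symbol that had the smallest p in edgeR were ADC1A, an arginine decarboxylase of the polyamine pathway (-0.61, SE 0.11, adjusted p = 0.0530), and SUT1, a sucrose transporter (-0.59, SE 0.11, adjusted p = 0.0570). Both lay below all CK libraries in 9 of 9 transgenic libraries. SUT1 stood at 146 ± 12.2 CPM in CK and a mean of 97.5 over the transgenic libraries. Next came a gene with the symbol cyclin (0.59), psi14B (-1.46), NtABS, a diterpene synthase of glandular trichomes (0.60), GolS1, a galactinol synthase (-1.37), the chaperone HSP101 (-1.30), hqt, of chlorogenic acid synthesis (-0.94), TAF-3 (-0.50), a gene with the symbol cyclase (0.68), the wound-induced KED (-0.80) and DXS, the entry enzyme of plastid isoprenoid synthesis (0.63), with adjusted p from 0.0652 to 0.111.

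Genes of water deficit and abscisic acid were lower in the transgenic lines as a set, with a median log2 change of -0.84 over 6 tested genes (-0.55 without CK replicate 2). None passed over all genes; 5 passed, all lower, adjusted over the list alone. These were GolS1 (-1.37, SE 0.27), GolS (-1.69, SE 0.48), NCED3-2 (-1.08, SE 0.38) and a pair of NCED3 copies, LOC107827644 (-0.61, SE 0.15) and LOC107799511 (-0.51, SE 0.16), where NCED is the enzyme that limits abscisic acid synthesis. P5CS, of proline synthesis, stood at 0.23 (SE 0.11) and did not pass. The 5 genes that passed are thus galactinol synthases and NCED3 copies only. GolS1 stood at 10.9 ± 5.64 CPM in CK and lay below all CK libraries in 6 of 9 transgenic libraries. GolS was near the floor at 1.42 ± 1.02 CPM in CK (7 of 9), and each gene of the NCED3 pair lay below in 8 of 9. Camera gave an adjusted p of 3.29e-05 with the preset correlation, and the call held with an estimated correlation (adjusted p = 0.0190) and in fry (adjusted p = 0.00615). The set passed in P2.4a (adjusted p = 0.000826), P3.9a (0.00598) and P9.10a (2.07e-05); with an estimated correlation these were adjusted p = 0.0493, 0.0979 and 0.0169. Against the others of their group, libraries lay from -0.42 (P9.10a replicate 3) to 0.45 (P3.9a replicate 1) in the median of this list.

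Heat shock genes were lower as a set, with a median of -0.39 over 7 genes and an adjusted p of 0.000163, lost with an estimated correlation (adjusted p = 0.116). Over the list alone 2 genes passed, HSP101 (-1.30, SE 0.26; 268 ± 108 CPM in CK) and the heat shock factor NtHSF1 (-0.73, SE 0.20), and no gene passed over all genes. Nthsp26a stood at -1.69 (SE 0.63) and did not pass. The set was lower in P2.4a (adjusted p = 0.0414), P3.9a (0.000101) and P9.10a (0.000722), and with an estimated correlation these calls were lost (adjusted p = 0.532, 0.0979 and 0.121). Against the others of their group, P2.4a replicate 3 lay at -0.61, P3.9a replicate 2 at -0.57, P9.10a replicate 3 at -0.48, CK replicate 2 at -0.43, CK replicate 1 at 0.43 and P3.9a replicate 1 at 0.34.

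In carbon metabolism, the starch and sucrose list was lower (median -0.25 over 8 genes, -0.13 without CK replicate 2, adjusted p = 0.00405; adjusted p = 0.116 with an estimated correlation, 0.0210 in fry). SUT1 and vi (-0.25, SE 0.09) passed over the list alone and none over all genes, while SPSA and SPSC, sucrose-phosphate synthases, had -0.29 (SE 0.11) and -0.71 (SE 0.31) and did not pass. In nitrogen metabolism, the nitrate and ammonium list was lower (median -0.24 over 10 genes, adjusted p = 0.0341), lost with an estimated correlation (adjusted p = 0.281) and without P3.9a replicate 1 (adjusted p = 0.142). No member passed over the list alone or over all genes; NtNRT1.1-t had -0.29 (SE 0.11), gdh1, a glutamate dehydrogenase, -0.51 (SE 0.22) and the nitrate reductase NIA1 -0.44 (SE 0.21). Leaving out CK replicate 1 or 3, P2.4a replicate 3 or P9.10a replicate 1 also ended this call.

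Alkaloid genes were lower in all 7 tested members by sign (median -0.19, -0.30 without CK replicate 2, adjusted p = 0.00957; adjusted p = 0.123 with an estimated correlation). DAO1 (-0.85, SE 0.22) passed over the list alone, and QPT2A, of nicotine synthesis, had -0.28 (SE 0.13) and did not; libraries lay from -0.36 (P3.9a replicate 1) to 0.31 (P3.9a replicate 3) against the others of their group. The jasmonate and wounding list was lower (median -0.23 over 8 genes, adjusted p = 0.00354; adjusted p = 0.116 with an estimated correlation), with KED (-0.80, SE 0.18) and TIMPb (-0.76, SE 0.26) past the threshold over the list alone. The ethylene list was lower (median -0.12 over 18 genes, adjusted p = 0.00654; adjusted p = 0.423 with an estimated correlation), with the response factors NtERF#111 (-0.64, SE 0.17) and NtERF#193 (-0.69, SE 0.20) past it over the list alone. For ethylene genes libraries lay from -0.33 (P3.9a replicate 2) to 0.52 (P3.9a replicate 1) against the others of their group, and for jasmonate genes from -0.28 (CK replicate 1) to 0.39 (CK replicate 3). Without CK replicate 3 the ethylene list (adjusted p = 0.180) and the jasmonate list (0.0868) did not pass. The jasmonate median was -0.11 without P3.9a replicate 1, -0.12 without CK replicate 3 and -0.15 without CK replicate 2, and the ethylene median -0.21 without P3.9a replicate 1 and -0.23 without CK replicate 2. No gene of these 3 lists passed over all genes.

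Photosystem and light harvesting genes did not move past the threshold (median -0.08 over 14 genes, adjusted p = 0.139), with psbS, of non-photochemical quenching, at -0.32 (SE 0.14) and PSBR at -0.21 (SE 0.14); the list passed, lower, without CK replicate 1, P3.9a replicate 2 or P9.10a replicate 3 (smallest adjusted p = 0.0231), and its median ran from -0.14 without CK replicate 1 to -0.02 without CK replicate 3. Chlorophyll biosynthesis genes were higher (median 0.09 over 10 genes, adjusted p = 0.0341), a call lost with an estimated correlation (adjusted p = 0.423) and without CK replicate 1 or 3, P3.9a replicate 2 or P9.10a replicate 3. POR1, a protochlorophyllide oxidoreductase, had 0.66 (SE 0.16) and was the member that passed over the list alone; POR2 had 0.29 (SE 0.15). The chlorophyll median was 0.03 without CK replicate 1, 0.06 without P3.9a replicate 2, 0.14 without CK replicate 2 and 0.15 without P3.9a replicate 1. Carotenoid genes were lower (median -0.18 over 10 genes, adjusted p = 0.0341; adjusted p = 0.415 with an estimated correlation), with CRTISO (LOC107805441) at -0.21 (SE 0.09) and psy-1 at -0.25 (SE 0.13), and none past it over the list alone; the call was lost without CK replicate 2 (adjusted p = 0.0945), CK replicate 3, P2.4a replicate 2 or P9.10a replicate 1. Plastid ribosomal genes (median 0.06 over 7 genes, adjusted p = 0.501; CL28 0.12, CL27 0.08) and cytosolic ones (median 0.08 over 8 genes, adjusted p = 0.180; RPL3B 0.32, RPL3A 0.39) did not pass; the cytosolic list passed, higher, without P3.9a replicate 1 (adjusted p = 0.0408). With 1 library left out the plastid ribosome median ran from 0.00366 (CK replicate 1) to 0.12 (P3.9a replicate 1) and the cytosolic one from 0.03 (P9.10a replicate 3) to 0.13 (P3.9a replicate 1). P3.9a replicate 1 lay below its group for chlorophyll biosynthesis (-0.41), plastid ribosomes (-0.48) and cytosolic ribosomes (-0.42). P9.10a replicate 3 lay above its group for plastid ribosomes (0.46), cytosolic ribosomes (0.38) and photosystem genes (0.33), P3.9a replicate 2 for plastid ribosomes (0.39) and chlorophyll biosynthesis (0.31), and P9.10a replicate 1 below it for photosystem genes (-0.43) and plastid ribosomes (-0.36).

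The phenylpropanoid list was lower (median -0.05 over 30 genes, adjusted p = 0.0341), lost with an estimated correlation (adjusted p = 0.453) and without P3.9a replicate 1 (adjusted p = 0.489, median 0.04), which lay at -0.41 against the other libraries of its line for this list (P3.9a replicate 3 at 0.49), or without CK replicate 3, P2.4a replicate 3 or P9.10a replicate 2. hqt (-0.94, SE 0.19) passed over the list alone, and CAD14, a cinnamyl alcohol dehydrogenase, had -0.38 (SE 0.12). The median of this list was -0.01 without P2.4a replicate 3, -0.12 without CK replicate 2, -0.11 without P2.4a replicate 2 or P3.9a replicate 3, -0.09 without P3.9a replicate 2 and -0.07 without CK replicate 1 or P9.10a replicate 3. Pathogenesis-related genes did not pass (11 genes, adjusted p = 0.643), with a median of -0.02 (-0.16 without CK replicate 2, 0.11 without P9.10a replicate 1) against an upward direction in the test; TLP1, a thaumatin-like protein, had 1.08 (SE 0.37) and PR-1B -0.89 (SE 0.62). In all, 11 of the 15 lists passed, 2 higher and 9 lower; 1 passed with an estimated correlation and 5 in fry. Adjusted over all 25 lists these counts were 11, 1 and 2. Leaving out CK replicate 3 left 4 lists. With the preset correlation, other regroupings of the 12 libraries passed a median of 3 lists.

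**Figure D3:**
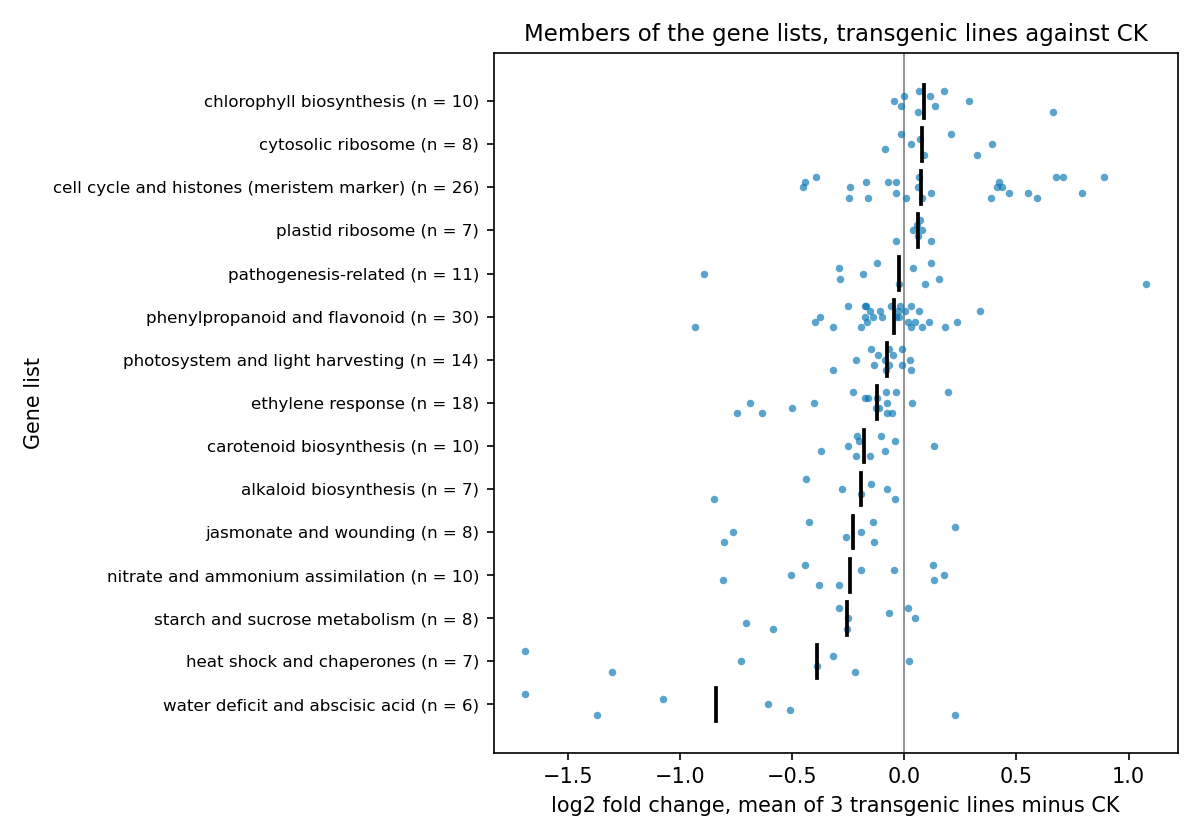
Fitted log2 fold change of the mean of 3 transgenic lines minus CK (horizontal axis) for each tested member of 15 gene lists (vertical axis, with the number of members); points are genes, spread vertically for legibility, and black bars are list medians. The water deficit list has the lowest median, -0.84, and the heat shock list the next, -0.39.

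Markers of other cell types were few. Dividing-cell and histone genes were higher as a set (median 0.07 over 26 genes, adjusted p = 0.0341; adjusted p = 0.423 with an estimated correlation), lost without P3.9a replicate 1 (adjusted p = 0.142), CK replicate 2 or 3, P2.4a replicate 3 or P9.10a replicate 1. The gene with the symbol cyclin (LOC107793085; 0.59, SE 0.11) and CycD3.1, a D-type cyclin (0.43, SE 0.12), passed over the list alone. The median was 0.18 without CK replicate 1, 0.13 without CK replicate 2, 0.11 without P9.10a replicate 2 and 0.05 without CK replicate 3 or P3.9a replicate 1. P2.4a replicate 3 lay 0.58 above the other libraries of its line for this list, with 21 of 26 genes above each of them. NtABS was the 1 trichome marker (0.60, SE 0.12; above all CK libraries in 8 of 9; adjusted p = 0.0760 over all genes), TobRB7 the 1 root marker (0.05, SE 0.37), and the flower markers FUL1 (-0.06), FUL2 (0.31) and SOC1 (-0.08) and the vascular markers SEO1 (0.14), SEO2 (0.18) and COV1 (0.06) did not pass. Lists with fewer than 5 tested members had no set test: the Calvin cycle genes GAPA, GAPB and a pair of Rca copies had a median of -0.08, SEN4, the 1 senescence gene, had -0.58 (SE 0.18), cnd41, a chloroplast protease, had -0.08 and the phosphate transporter PT1 had -0.08, none past it over all genes.

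Each line was compared with CK on its own. In P2.4a, 3 genes passed. LOC107794724 rose 2.14-fold (log2 change 1.1, SE 0.15, adjusted p = 0.0273), LOC107772409 fell by 2.74 (SE 0.30, adjusted p = 0.00620) and LOC107781523 by 2.07 (SE 0.26, adjusted p = 0.0273), from 15.7 ± 3.26 to 3.75 ± 0.780 CPM. No named gene passed in edgeR with all libraries, 124 had an unadjusted p under 0.05 and DESeq2 called 7. Without P3.9a replicate 1, edgeR called 3 named genes. The smallest p with all libraries were those of Hxk1, a hexokinase (1.1, SE 0.18, adjusted p = 0.190), the gene with the symbol cyclin (0.75, adjusted p = 0.197) and SUT1 (-0.64, adjusted p = 0.271). DESeq2 called 138 genes and edgeR on the 6 libraries alone 238; leaving out P3.9a replicate 1 gave 56, P3.9a replicate 3 gave 9, CK replicate 3 gave 5, P2.4a replicate 1 gave 1 and CK replicate 1 gave 0, where 4052 genes had an unadjusted p under 0.05 with all libraries. Of the lists, 3 passed (1 adjusted over all 25 lists), all lower: water deficit, heat shock and ethylene. With an estimated correlation water deficit alone passed (adjusted p = 0.0493; none over all 25 lists), and heat shock and ethylene did not (adjusted p = 0.532 for each).

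In P3.9a, 14 genes passed, 6 higher and 8 lower. LOC107811420 rose 31.7-fold, from 26 to 43 counts per library in CK to 759 to 1410 (log2 change 4.99, SE 0.22, adjusted p = 1.33e-08). LOC107786896 rose 2.97-fold (1.57, SE 0.17, adjusted p = 0.00168). LOC107772409 fell by 3.42 (SE 0.31, adjusted p = 0.000372) and LOC107774583 by 1.22 (SE 0.15, adjusted p = 0.00631). NtABS was the 1 named gene past the threshold in edgeR, where 89 had an unadjusted p under 0.05, DESeq2 called 14 and edgeR without P3.9a replicate 1 called 8. It stood at 124 ± 11 CPM against 65.4 ± 3.29 in CK (0.92, SE 0.15, adjusted p = 0.0413); ADC1A (-0.80, adjusted p = 0.0544) and the gene with the symbol cyclase (1.05, adjusted p = 0.0549) came next. DESeq2 called 244 genes, edgeR without a filter 33 and edgeR on the 6 libraries alone 3. Leaving out P3.9a replicate 1 gave 105, P3.9a replicates 2 and 3 gave 5 and 8, CK replicates 1, 2 and 3 gave 7, 24 and 8, and P9.10a replicates 1 and 3 gave 8 and 7. Of the lists, 10 passed (9 over all 25 lists), of which pathogenesis-related genes were higher (median 0.30, adjusted p = 0.0397; adjusted p = 0.359 with an estimated correlation), and none passed with an estimated correlation.

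In P9.10a, 5 genes passed, 2 higher and 3 lower. LOC107805125 rose 8.85-fold, from 3.13 ± 0.127 CPM to 27.8 ± 16.5 (log2 change 3.15, SE 0.39, adjusted p = 0.0279), and LOC107786896 rose 2.44-fold (1.29, SE 0.17, adjusted p = 0.0217). LOC107780718 fell by 2.41 (SE 0.32, adjusted p = 0.0279) and LOC107772409 by 2.33 (SE 0.29, adjusted p = 0.0167). ADC1A (-0.71, adjusted p = 0.163), NtABS (0.72, adjusted p = 0.198) and SUT1 (-0.61, adjusted p = 0.228) had the smallest p among named genes and did not pass. In edgeR 90 named genes had an unadjusted p under 0.05, and DESeq2 called 11. Without P3.9a replicate 1, edgeR called 1 named gene. DESeq2 called 153 genes, edgeR without a filter 9 and edgeR on the 6 libraries alone 16. Leaving out P3.9a replicate 1 gave 12, P2.4a replicate 2 gave 8, CK replicates 1, 2 and 3 gave 2, 10 and 3, and P9.10a replicates 1 and 3 gave 3 and 1. Of the lists, 9 passed with either family, 2 higher and 7 lower, and the water deficit list alone held with an estimated correlation.

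The 3 lines differed from each other in 3 genes by the F test. These were LOC107811420, high in P3.9a (adjusted p = 1.88e-09), LOC107800858, lower in P9.10a at 9.30 ± 0.901 CPM against 19.6 ± 1.30 in CK (adjusted p = 0.00177), and LOC107805125, high in P9.10a (adjusted p = 0.0191). The next smallest p were those of LOC107765628 (adjusted p = 0.0558), under the log2 CPM limit for naming at 0.679, and LOC107826117 (0.0673). Neither passed, and no named gene passed in edgeR (41 had an unadjusted p under 0.05, and DESeq2 called 3): Hxk1, NtABS, FAD2, an oleate desaturase, and NtPDR1, an ABC transporter, had adjusted p from 0.228 to 1.00. DESeq2's likelihood ratio test called 46 genes, and leaving out P3.9a replicate 3 gave 6.

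Of the 3, 14 and 5 genes called in P2.4a, P3.9a and P9.10a, 2 genes were called in more than 1 line. LOC107772409 was lower in all 3 and LOC107786896 higher in P3.9a and P9.10a. A call in 1 line only does not show that the lines differ. By the F test among lines, 1134 genes had an unadjusted p under 0.05, where 1960.4 are expected by chance. A count below the expected one does not show that the lines are alike, and its cause was not tested. In 20 simulations of unchanged groups that shared 1 simulated CK group, at most 1 gene was called in 2 or more lines. The simulations drew each gene independently and held no library that stood apart, in CK or in the lines. Independent lists would share at most 0.000612 genes in 1 direction for any pair. Across genes, which are not independent replicates, log2 changes of pairs of lines correlated at 0.596 for P2.4a and P3.9a, 0.714 for P2.4a and P9.10a and 0.680 for P3.9a and P9.10a. Simulated shared controls alone gave 0.495, 0.496 and 0.496. The covariances were 0.0746, 0.0868 and 0.0782 against 0.0399, 0.0402 and 0.0402 simulated. The 3 CK libraries are too few to split, so part of the overlap may come from the shared controls. Overlap counts were 96 with DESeq2, 4 without a filter, and without P3.9a replicate 1, CK replicate 2 and CK replicate 3 they were 19, 8 and 4; without CK replicate 1 or P9.10a replicate 3 the count was 1.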

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

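The neighbour test here was set before its result was seen; that the genes and lists differ was read from planned tests among the lines. LOC107811420 differed among the 3 lines (adjusted p = 1.88e-09), with 759 to 1410 counts in P3.9a against 26 to 43 in the other 9 libraries. LOC107805125 (adjusted p = 0.0191) stood at 199 to 672 counts in P9.10a against 45 to 59 elsewhere, and LOC107800858 (adjusted p = 0.00177) at 126 to 159 counts in P9.10a against 285 to 389 elsewhere. All 3 follow a line, and the labels trace the lines to primary transformants, so an effect of a transformation event, such as where the construct landed, may account for them. A change of the whole chromosome region was tested with the neighbours in the reference order, 5 on each side, pooled over the 3 genes. Of 15 tested neighbours, 0 moved the same way at an edgeR unadjusted p under 0.05, with an exact upper 95% limit of 21.8%. That limit is for the pooled neighbours and was not computed for each gene, which has fewer. It also treats the 15 neighbours as independent, while neighbours of 1 gene would move together in such a change. The limit therefore does not decide on a shift of the whole region, although no tested neighbour passed in the direction of its gene. A change that touches a single gene or acts in opposite directions is open too. Beside LOC107811420, 2 neighbours fell in P3.9a, LOC107811419 by 1.26 (edgeR unadjusted p = 0.00726) and LOC107769270 by 0.54 (edgeR unadjusted p = 0.0312), noted after their values were seen. Reads shared with near-identical copies and sequence differences between lines were not tested and stay open. For the number of genes that differ among the lines, 3 of 100 regroupings of the 9 transgenic libraries, the real one included, gave 3 or more genes. That share is under the bound of 0.05 set for excluding chance. The 2 others gave more than the real one, 4 each, and the draws were extended to 100 after the first were seen.

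Several lists differed between lines by camera, each lost with an estimated correlation (adjusted p from 0.162 to 0.654). Adjusted over all 25 lists, phenylpropanoids between P2.4a and P3.9a were also lost (adjusted p = 0.0610), and the others held. P2.4a lay above P3.9a in nitrate and ammonium genes (adjusted p = 0.00258) and phenylpropanoids (0.0488) and below it in pathogenesis-related genes (0.000162). P2.4a lay above P9.10a in phenylpropanoids (9.56e-05) and below it in pathogenesis-related genes (0.00875). P3.9a lay below P9.10a in photosystem (0.00761), chlorophyll biosynthesis (0.0158) and plastid ribosome genes (0.00168). P3.9a replicate 1 lay below the other P3.9a libraries in plastid ribosome (-0.48), chlorophyll biosynthesis (-0.41), phenylpropanoid (-0.41) and nitrate (-0.27) genes, and P3.9a replicate 3 above in phenylpropanoids (0.49). P9.10a replicate 3 lay above its line in plastid ribosome (0.46) and photosystem (0.33) genes and P9.10a replicate 1 below it (-0.36 and -0.43). In pathogenesis-related genes P9.10a replicate 1 lay at -0.44 and replicate 2 at 0.40, and P2.4a replicate 2 at 0.22 and replicate 3 at -0.26. In phenylpropanoids P2.4a replicate 2 lay at 0.37 and replicate 3 at -0.28, and P9.10a replicate 2 at -0.22. In nitrate genes P2.4a replicate 1 lay at 0.50 and replicate 3 at -0.26, and P3.9a replicate 2 at 0.38.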

How the results depend on the processing

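Chosen after seeing the data were thinning, the means of 2 lines, the adjusted p of 0.1, and the adjustment over all 25 lists, which kept 11. The cause of a changed count was not tested except where stated. Genes called in the mean of the 3 lines numbered 15. DESeq2 gave 453 and limma with line as a random block 486, where limma's estimated correlation within lines was -0.102. With a negative correlation the block allows for no spread between lines, so 486 is not a count with the lines as replicates. No filter gave 82, a fold limit of 1.5 gave 3, library sizes without the 20 most abundant genes gave 23, 1 draw of thinning to equal depth gave 34 and 10 others 11 to 35, and an adjusted p of 0.1 gave 197. The mean of 2 lines gave 27 without P2.4a, 2 without P3.9a and 8 without P9.10a, and 1 gene was called in each line alone. Counts with 1 library left out ran from 6 to 740. For P2.4a, DESeq2 gave 138 and the fit of 6 libraries 238, with 0 to 56 when 1 library was left out. For P3.9a these were 244 and 3, with 5 to 105; no filter gave 33 and an adjusted p of 0.1 gave 45. For P9.10a they were 153 and 16, with 1 to 12, and no filter gave 9. Among the 3 lines DESeq2 gave 46, an adjusted p of 0.1 gave 5, and leaving out 1 library gave 2 to 6. Genes called in 2 or more lines numbered 96 with DESeq2, 4 without a filter and 1 to 19 with 1 library left out. An estimated correlation left 1 list and fry 5, and leaving out 1 library left 4 to 11. The other scalings kept every count within 1.5 times the reported one.

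Replicate numbers do not pair these libraries: correlations of same-numbered libraries ran from -0.309 to 0.265, 4 of 18 pairs were over 0.1, and 3 of 12 libraries correlated best with their own number. With the replicate number as a block, the mean of the 3 lines gave 4 genes and P3.9a gave 4; the other counts stayed within 1.5 times.

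Of 50 named genes, 47 kept their direction in all of 25 settings. NtPDR1 turned to -0.0132 and LOC107826117 to -0.27 in the mean without P3.9a, LOC107826117 also ran from -0.0203 to 0.217 with 1 library left out, negative without CK replicates 1 and 2, and LOC107800858 to 0.0849 in the mean without P9.10a. All 11 lists past the threshold kept the direction of their test in 21 settings, while the phenylpropanoid median turned to 0.04 without P3.9a replicate 1; 43 of 231 values lost the threshold. The simulated recovery of 1.5-fold changes was 25.4%, so smaller changes were mostly not detectable in the simulation. It held no library that stood apart, so the recovery in the real libraries is not known from it. Larger changes also failed over all genes in edgeR, such as GolS1 (-1.37, adjusted p = 0.0786) and HSP101 (-1.30, adjusted p = 0.0849).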

Other observations

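Other groups of genes, added on reading the symbols, were tested in the mean of the 3 lines. Antioxidant enzymes and ferritin were lower (median -0.22 over 13 genes, 12 lower by sign, adjusted p = 0.0122 over all 25 lists), and endoplasmic reticulum chaperones were higher (median 0.64 over 8 genes, adjusted p = 0.0197), with the chaperone genes BIP3 at 0.69 (SE 0.29) and BIP4 at 0.78 (SE 0.36). Neither held with an estimated correlation (adjusted p = 0.469 for each), and for the chaperones P3.9a replicate 1 lay at -1.51 and replicate 3 at 1.05 against the other libraries of their line. The plastid isoprenoid list (median 0.12, adjusted p = 0.0623), cysteine proteases (-0.20, 0.135), autophagy genes (-0.09, 0.670), hexose kinases (0.02, 0.266), amino acid biosynthesis (0.07, 0.741), photosynthetic electron transport (-0.14, 0.435), other tetrapyrrole genes (0.08, 0.586) and rapidly elicited defence genes (-0.18, 0.215) did not pass; 3 gibberellin genes had a median of -0.03.

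Adjusted over the 906 named genes alone, a family chosen after seeing the data, 17 passed in edgeR, 6 higher and 11 lower. Beside those already named they include IPS (-0.65), MET1 (0.89), ASF-1/G13 (-0.60) and dnaJ (-1.11). All 9 transgenic libraries lay above all CK libraries in 353 genes and below them in 677, where chance gives a mean of 178.2 genes each way, 0.4545%. Genes share the same libraries, so a single split can lie far from this mean. The spread over other splits was not computed, so these counts are not shown to be beyond chance. LOC107773975 had 0 counts in each CK library and 4 to 40 in each transgenic library, at least 25.0-fold higher against a floor of 3 counts over the CK group; its edgeR adjusted p was 0.0513, and it was chosen after its values were seen.

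The tests on the spread and on depth were chosen after the counts were seen; the regroupings were not, but were extended to 100 after the first were seen. The bound for excluding depth was first a comparison of medians, which would have excluded it, and was changed to ranges apart after its result was seen. Few genes passed in the mean of the 3 lines although many more than expected had a small p. A higher depth of CK stays open: in 10 draws thinned to equal totals a median of 21.5 genes passed (11 to 35), and in 10 thinned by 1 fraction to the same summed depth 27.5 (14 to 50), ranges that overlap. A raised spread from 1 library remains a candidate explanation: 740 genes passed without P3.9a replicate 1, against at most 48 without any other library, and 15 of the 15 remained among them. The contrasts of P2.4a and P9.10a with CK hold no P3.9a library. They gave 3 and 5 genes with all libraries and 56 and 12 without P3.9a replicate 1. There it can act only through the shared fit, and both rises go with a raised spread, which was not itself compared. What sets that library apart was not tested, and it was kept, since its own values are the ground for doubting it. For the 15 genes, 2 of 100 regroupings of the 12 libraries, the real one included, gave as many, which excludes chance at 0.05, but the other gave 506 genes. That one set CK replicates 1 and 3 and P3.9a replicate 1 against the rest. Such a count points to a structure of the samples, but 2 of the 3 controls were real ones and P3.9a replicate 1 was taken out of its line. CK replicates 1 and 3 with P2.4a replicate 1, P3.9a replicate 3, P9.10a replicate 1 or P9.10a replicate 2 as controls gave 0 genes. These values argue against the 2 real controls alone. CK replicates 2 and 3 with P3.9a replicate 1 gave 2 genes, and what gave 506 was not tested further. For the 11 lists 1 of 100, the real one, gave as many, with 9 in the highest other, so chance is excluded at 0.05 for their number with all 12 libraries. Without CK replicate 3 the lists numbered 4, inside the range of the other regroupings. Regroupings without that library were not run, so the test does not tell a difference between groups from an effect of CK replicate 3. The other regroupings passed a median of 3 lists with the preset correlation, so this test does not exclude chance for any single list. Each line against CK has 10 splits, too few for a share under 0.05: the real split was 1 of 10 in each line, with 3, 14 and 5 genes and 0, 1 and 0 in the highest other split.

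The tests in this paragraph were chosen after the lists were seen. Water deficit and heat shock genes were lower in the transgenic lines. With 1 CK library left out, the highest camera adjusted p of both lists was 0.016 with the preset correlation, that of heat shock without CK replicate 1. This argues against a single CK library at the preset correlation only. Fits with 1 CK library left out were not run with an estimated correlation, so for heat shock the test does not decide. With an estimated correlation and all libraries, water deficit held (adjusted p = 0.0190) and heat shock did not (0.116). Younger or more actively dividing leaf tissue in the lines may lower such genes too; the dividing-cell list was higher, but its adjusted p with an estimated correlation was 0.423, so this cannot be told apart from an effect of the transgene. Place in the field and time of sampling are not given in the labels used here, and they stay open beside a biological difference between transgenic and untransformed plants.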
